A study of Mus musculus with 12 samples.

How the data were processed

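Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run for the histone marks H3K27ac, H3K4me1 and H3K4me3 on cKit+ bone marrow cells of C57BL/6 mice. Wild type mice (WT) were compared with mice carrying Phf6 R274X as a transgene (Tg), with 2 libraries per genotype and mark and 12 libraries in all. Per the labels' protocols, the cells were purified on a BD FACSAria II, chromatin was crosslinked, sheared and precipitated with a Diagenode True MicroChIP kit, and single-end reads of 75 bp were made on a NextSeq 500 from MicroPlex libraries. Per the submitters' processing notes, FastQC, Trim Galore, Bowtie2, SAMtools, MACS2 and deepTools were used with build mm10. Their versions, their settings and the control library, if any, are not stated there.

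The authors deposited 1 peak list in narrowPeak format for each library. Each deposited peak carries its position, a ratio (the fold enrichment at the summit over the local background), a −log10 p-value, a −log10 q-value and a deposited score, which equals the whole part of 10 times the −log10 q-value. The lists hold no read counts, so the depth of each library is unknown and no interval or floor that needs it was computed. Fold enrichments and −log10 values depend on depth and were not compared between libraries. They served to rank peaks within a list, to set a stricter peak threshold as an alternative, and to work out a local background.

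Genes came from a RefSeq table of GRCm38.p6, the assembly called mm10, with 21883 protein-coding genes of unique symbol. That table gives no strand and no exons, so transcription start sites were unknown and the windows planned around them were replaced by windows around either annotated end of a gene. A peak counted as near a gene end within 1 kb of either end of a protein-coding gene, as in a gene only when it overlapped a gene farther in, and otherwise as outside. Coordinates are 1-based.

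Within a mark, overlapping or touching peaks of the 4 lists were merged into regions, and a region was present in a library with at least 1 bp of a peak. Regions present in both libraries of a genotype and absent from both of the other are called Tg-only and WT-only here. Their numbers were set beside those from the other two ways of splitting 4 libraries into 2 and 2, which number 3 with the genotype split. Similarity of lists was measured by the Jaccard index in base pairs. Numbers, widths and shares per library were compared by two-sided exact permutation tests, whose smallest possible p with 2 against 2 libraries is 0.333.

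The graded value per gene was the length covered by peaks within 10 kb of either gene end. It was changed to log2 after adding 500 bp and quantile normalized, for genes with a peak in the window in at least 2 of the 4 libraries. Tg was compared with WT in limma (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05, and every adjusted p for a single gene below is limma's. A gene is said to rise or fall only if it passed that threshold. Gene lists were compared on the same fit by limma's camera, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a mark. The second form tests on the few residual degrees of freedom that 4 libraries leave, so a call lost there is not thereby shown to be false. There were 20 lists, 11 of pathways and 9 of cell types: stem cell and self-renewal, Hoxa and Hoxb clusters, myeloid progenitor, leukaemia genes, JAK-STAT pathway, cell cycle, p53 targets, ribosome biogenesis, NuRD complex, NF-kB and TNF signalling, interferon response, erythroid, megakaryocyte, mature granulocyte, monocyte and macrophage, B-lymphoid, T-lymphoid, NK cell, mast cell and basophil, and stroma and endothelium. Of their members, Mx1, Mx2, Tpsab1 and Ahsp had no match in the gene table. Members of a list that lie next to each other share windows and peaks.

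A distal active region lay over 1 kb from every gene end, had H3K4me1 and H3K27ac in both libraries of a genotype and had H3K4me3 in neither. Whether the marks changed near the same genes was tested by 12 two-sided Fisher's exact tests across genes tested in both marks, adjusted together, and by Spearman correlations of the changes. Genes are not independent replicates in either.

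The tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. For each mark and direction the rule names the 6 genes with the largest change past the threshold, the 6 genes nearest within 10 kb to the strongest regions of a single genotype, at most 4 members per list that lie near such a region, and the 5 strongest such regions. Of the list members, only those in lists that passed are given values in the text, and some genes the rule names are left out of the text. Strength is the smaller of the 2 peaks' percentiles of −log10 q within their lists. Phf6, Kit and Xist are always given. Mpo and Lpo, Elane, Prtn3 and Cfd, and other loci given in kb of covered length were chosen after their values were seen, as were the counts at Y-linked genes.

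The local background, read at Vav1 and Phf6 and in tiles of 100 kb, was worked out from each peak's deposited fold enrichment and −log10 p-value, taking the fold as summit reads plus 1 over background plus 1 and the p as a Poisson tail, which is how MACS2 is built. The summit solved to a whole read number in 100% of peaks within 0.02 of the −log10 p-value. Background is given relative to the median of the library's own list.

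Alternatives covered the peak threshold (−log10 q of at least 5), 50% cover for presence, merging within 500 bp, lists of equal length (31257 peaks for H3K27ac, 100316 for H3K4me1 and 34920 for H3K4me3), the stronger 50% of each list, autosomes only, pseudocounts of 100 and 2000 bp, other scalings, no filter, windows of 2 and 50 kb, the replicate number as a block, and each library left out in turn. Where a genotype is left with a single library, limma pools the spread and that library is assumed to vary like the others.

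The code was tested on simulated data before use. It recovered all of 20000 simulated regions (100%), their presence in each library (100%), 2633 regions of a single genotype (100%), covered lengths at 200 genes (100%), distances to gene ends for 500 peaks (100%), and the background of 4693 peaks to within 1% in 99.957%. For Tg against WT in H3K27ac, with the spread of the 13076 real genes, limma recovered 0% of 100 genes changed by 1 on the log2 scale and 48% of 100 changed by 2. In H3K4me1 (15829 genes) it recovered 0% of both, and in H3K4me3 (15796 genes) 64% and 89%, with 8 false calls. With no simulated change it called 0 genes in each mark, and camera called 1 list in H3K4me3. Simulated genes varied independently, while real neighbours share windows and peaks. The simulation therefore cannot give camera's false calls in the real lists.

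The work used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Summit positions were not used here. The labels do not state the sex of the mice, whether the same animals gave all 3 marks or whether replicates came from separate animals. So p-values measure only the spread between these libraries, which may be technical. In H3K4me3 peaks at Y-linked genes and Xist told replicate 1 from replicate 2 in both labels. There the replicates were thus not from the same animal. H3K27ac had peaks at Xist and 0 at these Y-linked genes in every library, unlike H3K4me3 replicate 1. Results that combine the marks may therefore set animals of different sex side by side.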

Results

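The series asks whether the chromatin of blood stem and progenitor cells is altered in mice that carry Phf6 R274X, a truncating change in an X-linked gene mutated in leukaemia. H3K27ac marks active promoters and enhancers, H3K4me1 marks enhancers and their surroundings, and H3K4me3 marks active promoters. Each mark was profiled in 2 WT and 2 Tg libraries of cKit+ bone marrow cells. The H3K27ac lists held 42124 and 31257 peaks in WT and 33179 and 38839 in Tg. The H3K4me1 lists held 100316 and 130348 peaks in WT and 104781 and 121172 in Tg. The H3K4me3 lists held 39584 and 37147 peaks in the libraries labelled WT and 34920 and 36676 in those labelled Tg. Read depth is unknown. The peak names inside all 4 H3K4me3 lists carry the genotype opposite to the library's label, while those of the other 8 lists match, so every direction given for H3K4me3 is by label only.

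Phf6 (chromosome X, 52912214 to 52956961) had an H3K27ac peak at its annotated start in all 4 libraries, covering 2210 and 2064 bp in WT and 1988 and 2072 bp in Tg. Both genotypes have this peak, so it does not tell them apart. H3K4me3 also had a peak at the Phf6 start in all 4 libraries. Inside the gene there were 6 and 4 further H3K4me3 peaks in the libraries labelled WT and 0 in both labelled Tg. H3K4me1 had 1 and 6 peaks inside Phf6 in Tg and 0 and 1 in WT. Those H3K4me3 peaks and the Tg H3K4me1 peaks inside the gene stood on a raised local background, given below. They are not read here as gains of a mark alone. Kit (chromosome 5, 75574987 to 75656722) carried peaks of every mark in all 12 libraries. Xist had peaks in all 8 libraries of H3K27ac and H3K4me1 and in the replicate 2 H3K4me3 libraries of both labels, with 6 and 3 peaks, against 0 peaks in the replicate 1 libraries. Those replicate 1 libraries instead had H3K4me3 peaks at the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, where all other libraries had 0.

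H3K27ac asks which promoters and enhancers gained or lost activity in Tg cells. Mpo, Elane and Prtn3, which encode proteins of primary granules of myeloid cells, rose in Tg together with their neighbours Lpo and Cfd. Among the genes that fell were Mmp8, of the mature granulocyte list, and others in none of the lists, such as Mmrn2, Olfm4 and Cyp2j8. The Hoxa cluster carried more peaks in Tg, with 2 and 3 peaks in WT against 11 and 9 in Tg. In limma, 36 of 13076 genes changed, 15 rose and 21 fell, at 26 separate loci. With p not adjusted, 1645 genes were under 0.05.

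Around Mpo (chromosome 11, 87793784 to 87804412) H3K27ac peaks covered 3865 ± 1178 bp in WT and 10593 ± 624 bp in Tg (SD, n = 2 each), a log2 change of 1.66 ± 0.17 (SE; limma adjusted p = 0.0489). Neighbouring Lpo changed by 2.25 ± 0.21, from 880 ± 433 to 4969 ± 1369 bp (adjusted p = 0.0445). The whole span of Mpo and Lpo held the same length of peaks as Mpo's window alone, so Lpo's peaks are counted for Mpo too. At the locus of Elane, Prtn3 and Cfd on chromosome 10, Elane rose by 1.52 (adjusted p = 0.0445), Prtn3 by 1.48 (adjusted p = 0.0445) and Cfd by 1.56 (adjusted p = 0.0466). That locus held 3.19 ± 0.248 kb of peaks in WT and 8.04 ± 0.549 kb in Tg. Prtn3's window alone held the same length, so Elane and Cfd add no peaks of their own and their calls are not independent of it. Slc46a1 rose by 1.81 (adjusted p = 0.0445) and Tmprss7 by 1.58 (adjusted p = 0.0445). Cited4 was listed at 0 bp in both WT libraries and at 1297 ± 197 bp in Tg (adjusted p = 0.0445). The lowest Tg library lay above the highest WT library at each of these genes, which adds no support because limma selected them on these values.

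Tmem45a2 (chromosome 16, 57036967 to 57071346) had the largest fall, from 7098 ± 235 bp of H3K27ac peaks in WT to 0 bp in both Tg libraries (adjusted p = 0.0228). Mmrn2 went from 3481 ± 694 bp to 0 bp (adjusted p = 0.0265), Olfm4 from 3199 ± 571 bp to 0 bp (adjusted p = 0.0265) and Cyp2j8 from 3009 ± 1229 bp to 0 bp (adjusted p = 0.0445). Lypd11 fell by 2.63 on the log2 scale and Treml4 fell by 2.43, each with an adjusted p of 0.0265. Mmp8 (chromosome 9, 7558429 to 7568486) fell by 1.84, from 9460 ± 660 to 1851 ± 639 bp (adjusted p = 0.0488), and the span of Mmp8 and Mmp27 went from 12.9 ± 0.772 to 2.04 ± 0.552 kb. All 36 calls were lost (0 genes, with 851 and 1090 at an unadjusted p under 0.05) when WT replicate 1 or WT replicate 2 was left out. There were 83 calls without Tg replicate 1 and 114 without Tg replicate 2, of which 33 and 35 were among the 36. Scaling to equal total covered length left 3 genes, Mmrn2, Olfm4 and Tmem45a2, all of which fell, against 15 rises and 21 falls after quantile normalization. With the replicate number as a block 0 genes rose and 6 fell, so Mpo, Elane and Prtn3 lost their calls. The other two splits of the 4 H3K27ac libraries gave 0 genes each, with 202 and 523 at an unadjusted p under 0.05, and camera called 1 and 0 lists there against 5 by genotype.

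**Figure D1:**
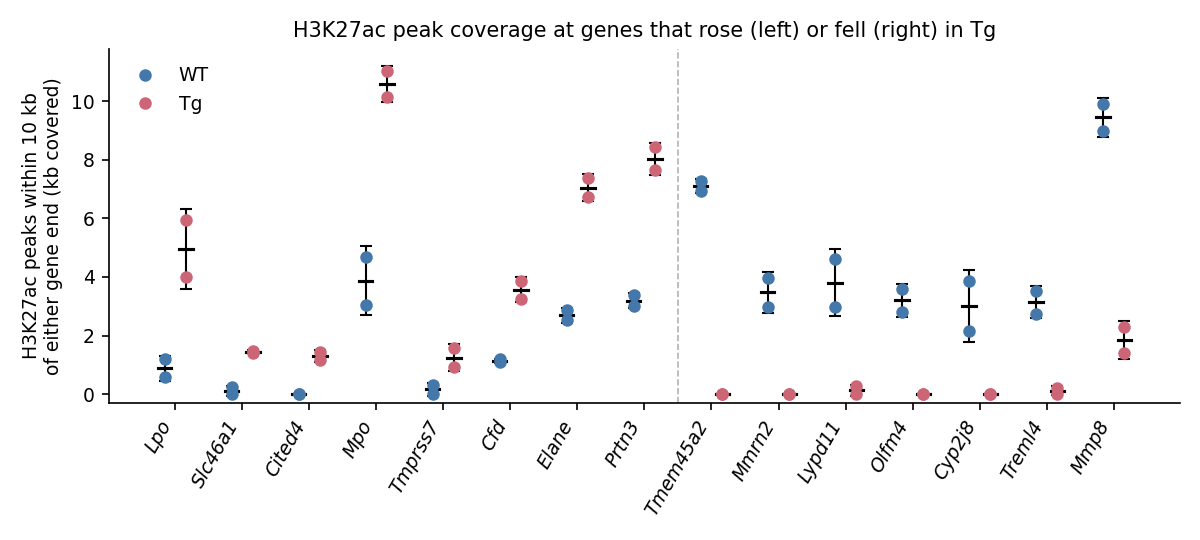
Length covered by H3K27ac peaks (kb, vertical axis) within 10 kb of either end of genes that rose or fell in limma; points are libraries, with the mean and SD of 2 WT and 2 Tg libraries. Mpo goes from 3865 to 10593 bp and Mmp8 from 9460 to 1851 bp, and Tmem45a2, Mmrn2, Olfm4 and Cyp2j8 are at 0 bp in both Tg libraries.

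Among the gene lists, the Hoxa and Hoxb clusters shifted up in H3K27ac (median log2 0.88, camera adjusted p = 1.66e-06, but adjusted p = 0.577 with an estimated correlation), with 14 of 15 tested members higher in Tg. Mature granulocyte genes shifted down (median -0.48, adjusted p = 3.36e-07), with 14 of 15 lower, and megakaryocyte genes did so too (median -0.34, adjusted p = 0.0192), each with adjusted p = 0.568 with an estimated correlation. Stem cell and self-renewal genes (median 0.15) and leukaemia genes (median 0.19) shifted up, each with an adjusted p of 0.0289 and adjusted p = 0.568 with an estimated correlation. For the megakaryocyte, stem cell and leukaemia lists the estimate (-0.0817, -0.00174 and 0.00958) lay below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these calls. With an estimated correlation camera tests on the few residual degrees of freedom that 4 libraries leave, so any call can be lost for lack of power. That test thus cannot tell a false list call from a true one in any of the 3 marks. For the Hox and granulocyte lists the estimate (0.459 and 0.0742) lay above the preset, which may then give too small a p. The Hox and granulocyte calls held without any single library. The megakaryocyte call was lost without WT replicate 1 (adjusted p = 0.213), WT replicate 2 (0.0752) or Tg replicate 1 (0.0742). The stem cell call was lost without Tg replicate 1 (0.142) or Tg replicate 2 (0.108), and the leukaemia call without WT replicate 1 (0.0600), Tg replicate 1 (0.0742) or Tg replicate 2 (0.108). Without normalization the median of all genes moved to -0.20, and the medians of the stem cell list (-0.13) and the leukaemia list (-0.04) lay below 0 yet above that shift.

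Over all genes, 0 members of the Hox list passed limma, while 11 rose and Hoxb1 fell adjusted over the list alone. Hoxa9 changed by 2.17 (adjusted p = 0.181), Hoxa7 by 1.96 (0.217), Hoxa10 by 1.79 (0.190) and Hoxa3 by 1.61 (0.237). Of the granulocyte list only Mmp8 fell over all genes, and 7 fell adjusted over the list alone, among them Ltf (-1.12, adjusted p over all genes 0.0911), Mmp9 (-1.39, 0.164), Ly6g (-1.22, 0.297), S100a8 and S100a9. The span of S100a8 and S100a9 held 40.2 ± 1.47 kb of peaks in WT and 21.5 ± 2.06 kb in Tg. Meis1, in the stem cell and leukaemia lists, changed by 1.94 (adjusted p = 0.0778), and within 10 kb of its ends Mecom was at 0 bp in WT and 1159 ± 830 bp in Tg (adjusted p = 0.122). Over the whole of Mecom with 10 kb on each side, where each WT library had 1 peak, H3K27ac covered 1.11 ± 0.222 kb in WT and 1.71 ± 0.495 kb in Tg, and over Meis1 taken likewise 0.764 ± 0.691 and 1.89 ± 0.844 kb. Adjusted over the list alone, 4 stem cell genes (Meis1, Mecom, Tal1 and Hoxb4) rose, 5 leukaemia genes rose and Lmo1 fell, and the megakaryocyte gene Itga2b rose while Tubb1, Vwf and F2rl2 fell. F2rl2 changed by -1.32 (adjusted p over all genes 0.202) and Vwf went from 451 ± 205 to 0 bp (0.247). Over all genes 0 members of these 3 lists passed. Mpo, Elane and Prtn3 of the myeloid progenitor list rose over all genes and adjusted over the list alone, but the list as a whole did not pass (median 0.06, camera adjusted p = 0.200).

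**Figure D2:**
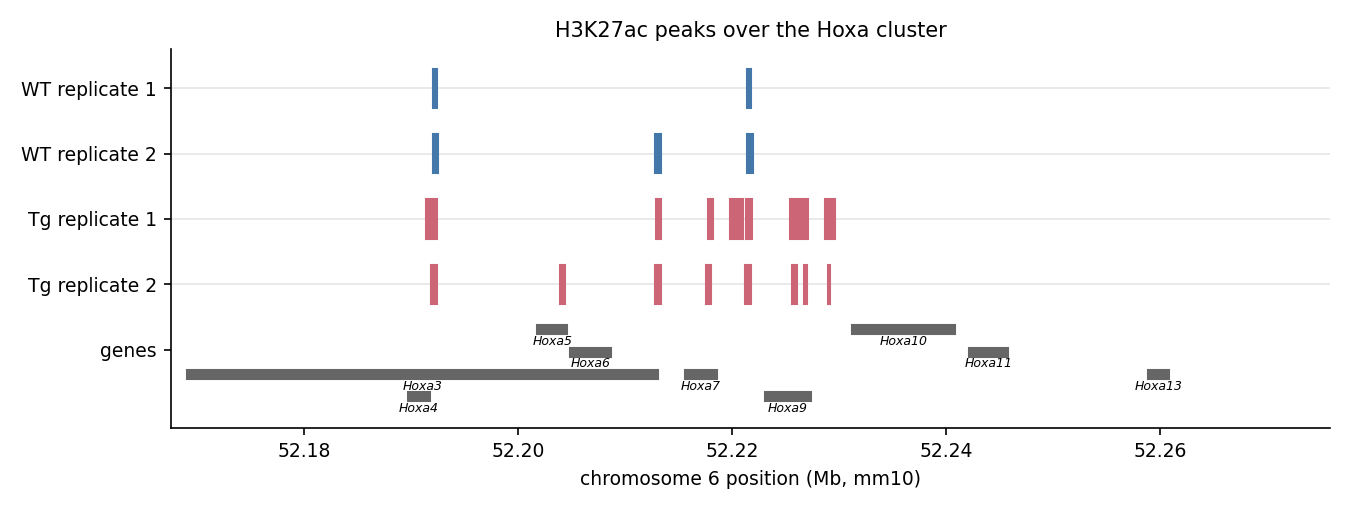
H3K27ac peaks (boxes) of each library along chromosome 6 (Mb, mm10) over Hoxa3 to Hoxa13, with the annotated genes drawn to scale underneath. Around Hoxa9 peaks cover 557 bp on average in WT and 3466 bp in Tg.

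The other 15 lists did not pass in H3K27ac. Medians were -0.13 for the JAK-STAT pathway, -0.06 for cell cycle, 0.10 for p53 targets, 0.15 for ribosome biogenesis, 0.07 for the NuRD complex, -0.03 for NF-kB and TNF signalling and 0.03 for interferon response. They were 0.18 for T-lymphoid, 0.28 for NK cell and 0.19 for mast cell and basophil genes, with 10, 3 and 4 members tested. In 4 lists the median, the mean and the direction of the test differed in sign: erythroid (median -0.02, mean 0.10, test up), monocyte and macrophage (-0.05, 0.02, down), B-lymphoid (0.10, -0.04, down) and stroma and endothelium (0.19, -0.15, down). Adjusted over the list alone, members passed in the erythroid list (Tal1 up and Tfrc down among them), the B-lymphoid list (Igll1 and Vpreb1 up, Cd74, Bank1 and Cd79a down) and the monocyte list (Mertk up, Lyz2 down). So did Il4 (up, mast cell and basophil list) and Col1a1 (down, stroma and endothelium list). None of these passed over all genes.

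**Figure D3:**
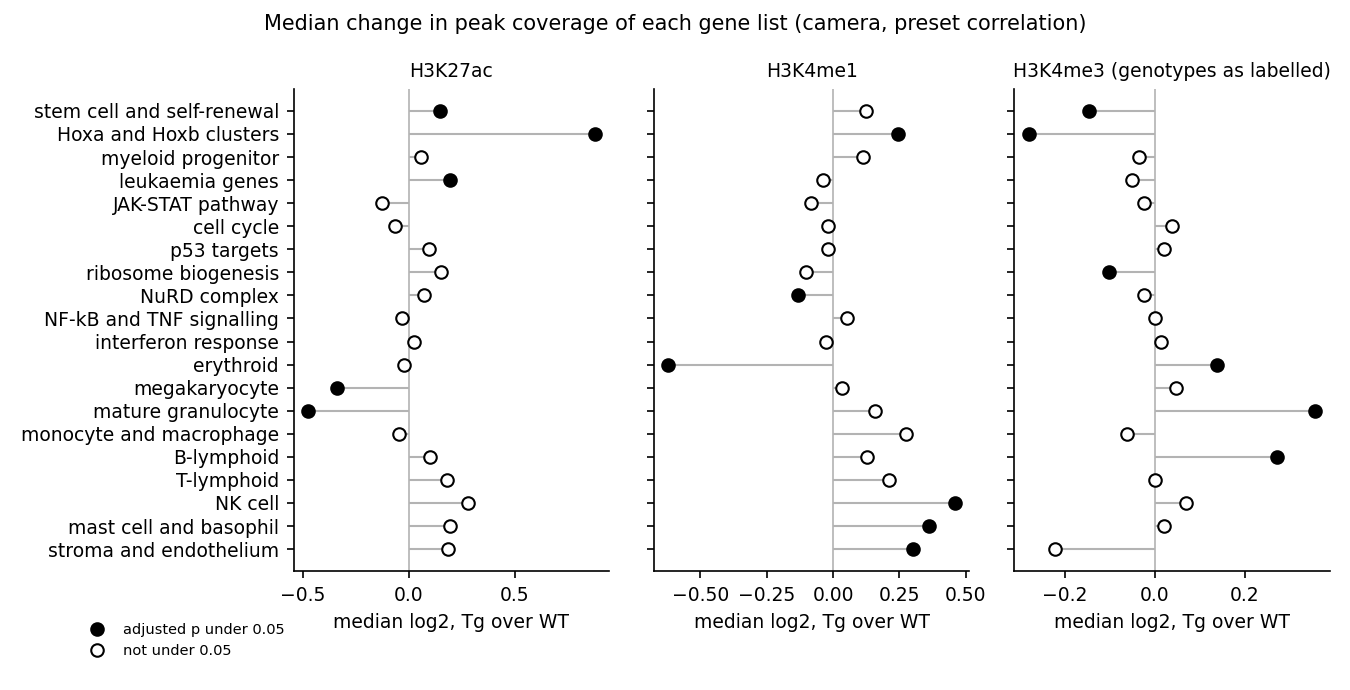
Median log2 change (horizontal axis) of peak coverage in Tg over WT for each of 20 gene lists and 3 marks; filled points have a camera adjusted p under 0.05 with the preset correlation of 0.01. The Hox clusters lie at 0.88 in H3K27ac and the erythroid list at -0.62 in H3K4me1, and no filled point keeps an adjusted p under 0.05 with an estimated correlation.

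Hoxa9 and Slc46a1 lay near strong regions found only in Tg, and Tmem45a2 and Mmp27 near strong regions found only in WT. Of 48376 merged H3K27ac regions, 19612 (40.5%) were present in all 4 libraries, 939 were Tg-only and 2371 WT-only. The strongest Tg-only regions near genes lay by Efna1 (chromosome 3, 89284789 to 89285910), Gm525, Hoxa9 (chromosome 6, 52225425 to 52226160), Slc46a1, Trim47 and Vps11. The strongest WT-only regions near genes lay over Tmem45a2 (chromosome 16, 57066064 to 57072314) and by Chil1, Mmp27, Thbs1, Zmpste24 and Psmb9. Away from gene ends, the strongest of the Tg-only regions lay at chromosome 12, 77211282 to 77212425, 25004 bp from Fut8, with others at chromosome 9, 3011521 to 3011876, and in Csmd1 (chromosome 8, 16794313 to 16794772). WT-only regions in Astn2 (chromosome 4, 66188249 to 66190378), Pde4b (chromosome 4, 102538134 to 102539435) and Blm (chromosome 7, 80503935 to 80505643) and near Plcb4 (chromosome 2, 135627209 to 135629162) led the other direction and ranked higher within their lists. Of the Hox list 7 members lay near a Tg-only and 0 near a WT-only region, and of the granulocyte list 1 (Cxcr2) and 8. Socs3, Cish, Il6ra, Csf2rb and Ptpn6 of the JAK-STAT list lay near WT-only regions, and 0 members of that list near Tg-only ones.

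Most of these regions were weak and lay away from gene ends. Only 11.2% of Tg-only and 8.35% of WT-only H3K27ac regions were near a gene end, against 44.2% of those in all 4 libraries, and their median widths were 493 and 637 bp against 1697 bp. The split that put WT replicate 1 with Tg replicate 2 gave 2362 and 251 regions, and the split by replicate number gave 318 and 667. With a library left out, its genotype needs a peak in only 1 library and the other needs absence from only 1, so both counts rise by construction and unequally. Without Tg replicate 1 there were 3160 WT-only and 5179 Tg-only regions, and in the full set 4040 regions are in Tg replicate 2 alone. Without WT replicate 1, WT replicate 2 or Tg replicate 2 there were 4705, 12191 and 5296 WT-only against 2330, 1302 and 3198 Tg-only regions. Peak number was 36691 ± 7684 in WT and 36009 ± 4002 in Tg (log2 -0.02, exact permutation p = 1), with a spread between the WT lists that could hide a difference. Peaks were wider in both WT libraries (1128 ± 60.4 bp) than in both Tg libraries (865 ± 8.71 bp), and covered 41.2 ± 6.45 against 31.2 ± 3.78 Mb, each with an exact permutation p = 0.333, the smallest possible. Near gene ends lay 28.6% ± 4.48 of peaks in WT and 30.6% ± 2.72 in Tg (SD, n = 2, exact permutation p = 0.667). The Jaccard index was 0.641 within genotypes and 0.578 between them, a difference of 0.0630, which nearly vanished without WT replicate 1.

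**Figure D4:**
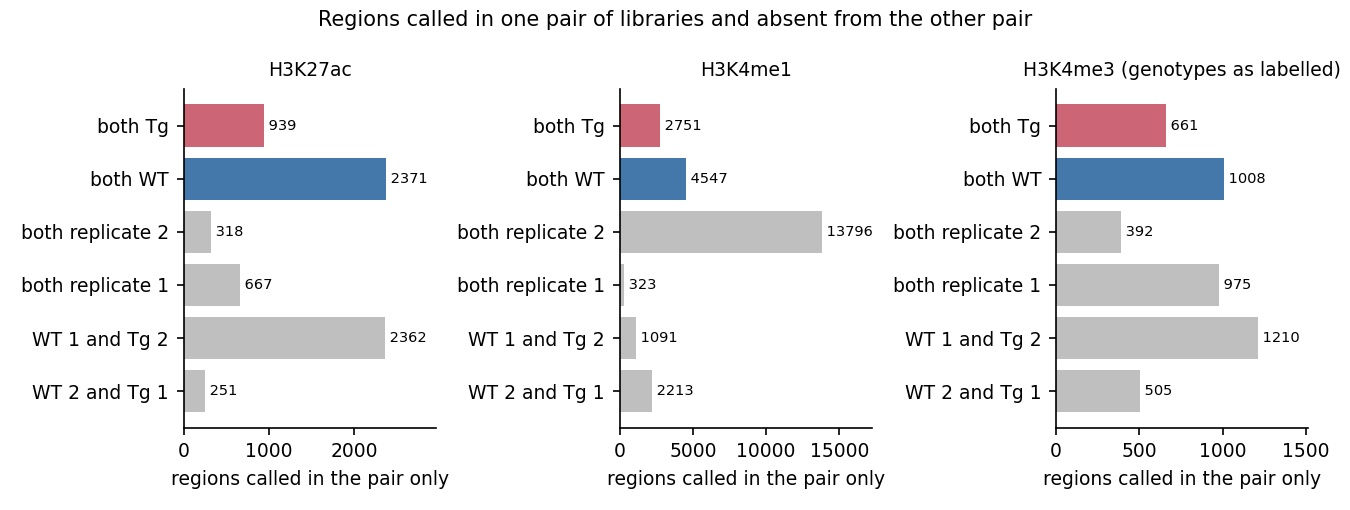
Number of merged regions (horizontal axis) present in both libraries of a pair and absent from both of the other pair, for each mark; coloured bars split the libraries by genotype and grey bars in the other two ways. The pair of replicate 2 libraries of H3K4me1 has 13796 such regions, the highest bar of the 3 marks, and H3K27ac has 939 Tg-only and 2371 WT-only regions.

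H3K4me1 asks whether the enhancer landscape itself changed. Erythroid genes, among them the globin genes Hbb-bt and Hba-a2, had less H3K4me1 as a group with the preset correlation, as did NuRD genes. The Hox clusters and genes of stroma, mast and NK cells had more, and each of these lists had adjusted p = 0.651 with an estimated correlation. At the myeloid loci that changed in H3K27ac the H3K4me1 means were close beside a wide spread. They were 10.4 ± 6.50 kb in WT and 12.3 ± 5.45 kb in Tg at Mpo and Lpo. At Mmp8 and Mmp27 they were 15.6 ± 6.86 kb in WT and 15.1 ± 7.13 kb in Tg. In limma 0 of 15829 genes passed, with 1262 at an unadjusted p under 0.05. On simulated data with this mark's spread limma recovered 0% of genes changed by 2 on the log2 scale. The 0 calls therefore do not show that H3K4me1 was unchanged. Camera called 6 lists by genotype, 2 by replicate number and 0 in the crossed split.

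The erythroid list shifted down in H3K4me1 (median -0.62, camera adjusted p = 2.29e-06), with 18 of 19 members lower in Tg. Adjusted over the list alone Hbb-bt, Zfpm1 and Hba-a2 were among 5 members that fell, and over all genes 0 did. Hbb-bt changed by -2.05, from 3809 ± 1548 to 688 ± 972 bp (limma adjusted p = 0.508) and Zfpm1 by -1.15 (0.515), and Hba-a2 was at 0 bp in both Tg libraries against 767 ± 656 bp in WT. Across the span of Hba-a1 and Hba-a2 peaks covered 0.903 ± 0.464 kb in WT and 0 kb in Tg. Klf1, Epor and Rhag were among 11 erythroid genes near WT-only regions and 0 near Tg-only ones. The call held without any single library, with adjusted p between 2.48e-06 and 0.00386, and was lost with an estimated correlation (adjusted p = 0.651 with an estimated correlation).

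Stroma and endothelium (median 0.30, adjusted p = 0.0199), mast cell and basophil (0.36, 0.0286), NK cell (0.46, 0.0363) and Hox genes (0.25, 0.0363) shifted up in H3K4me1, and NuRD genes shifted down (-0.13, 0.0322). All 5 had adjusted p = 0.651 with an estimated correlation. Each was lost without some library. Without WT replicate 1 the adjusted p was 0.719 for Hox, 0.735 for NK and 0.112 for the stroma, mast and NuRD lists. Without WT replicate 2 it was 0.0514 for NuRD. Without Tg replicate 1 it was 0.112 for NK and NuRD and 0.128 for stroma. Without Tg replicate 2 it was 0.372 for Hox and 0.103 for the NK, mast and NuRD lists. Adjusted over the list alone, Lepr, Sparc, Col1a2 and Pdgfrb of the stroma list rose, and 0 members of the other 4 lists passed, while over all genes 0 of any list did. Chd4, Hdac1, Mta1, Rbbp4, Rbbp7, Mbd2, Mbd3 and Cdk2ap1 of the NuRD list lay near WT-only regions, Gatad2a near a Tg-only region and Mta3 near regions of both kinds, with log2 changes of -0.90 at Rbbp7 (limma adjusted p = 0.508), -0.69 at Mta1 (0.527) and -0.57 at Mbd2 (0.656). Sparc went from 0 to 846 ± 462 bp (0.508), and Pdgfrb changed by 1.01 (0.515).

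The other 14 lists did not pass in H3K4me1. Medians were 0.12 for stem cell, 0.11 for myeloid progenitor, -0.08 for JAK-STAT, -0.02 for p53, -0.10 for ribosome biogenesis, 0.05 for NF-kB, -0.02 for interferon, 0.03 for megakaryocyte, 0.16 for mature granulocyte, 0.27 for monocyte, 0.13 for B-lymphoid and 0.21 for T-lymphoid genes. The leukaemia list had a median of -0.04 and a mean of -0.01 with the test up, and the cell cycle list a median of -0.02 and a mean of 0.03 with the test up. Of these lists 0 members passed over all genes or adjusted over the list alone.

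The strongest Tg-only H3K4me1 region lay 5432 bp from Vav1 (chromosome 17, 57271174 to 57273667), at the 99.2 percentile of its lists in the weaker of both Tg libraries. Its peaks stand on a local background of 10.7 to 11.7 times the list median, so it is not read here as a gain of H3K4me1 alone. Cep120, Dusp5, Nxpe5, Ebpl and Gm26637 followed, and regions in Smyd3 (chromosome 1, 179232262 to 179232661) and at chromosome 6, 82834985 to 82835792, chromosome 17, 79443909 to 79445473, and chromosome 4, 149845003 to 149845342, led those far from gene ends. WT-only regions lay by Mast1 (chromosome 8, 84936396 to 84937740), Nckipsd, Wipf2, Map3k6, Bsg and Khsrp, and in Tmem120b (chromosome 5, 123092390 to 123094066). Of 139885 regions 46121 (33.0%) were in all 4 libraries, 2751 were Tg-only and 4547 WT-only. The pair of replicate 2 libraries had 13796 regions to itself and the pair of replicate 1 libraries 323. The replicate 2 lists covered 120 and 117 Mb and the replicate 1 lists 66.3 and 70.7 Mb. With a library left out, which changes both rules unequally, Tg-only and WT-only counts were 3440 and 26075 without WT replicate 1, 16005 and 12123 without WT replicate 2, 20415 and 5589 without Tg replicate 1, and 9263 and 13619 without Tg replicate 2. The Jaccard index was 0.472 within and 0.495 between genotypes, and highest between WT replicate 2 and Tg replicate 2 (0.631). Near gene ends lay 17.5% ± 0.464 of peaks in WT and 16.9% ± 2.13 in Tg (exact permutation p = 1).

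H3K4me3 asks whether promoters changed. In the libraries labelled Tg, B-lymphoid, mature granulocyte and erythroid genes had more H3K4me3 as groups. Hox genes, stem cell genes and ribosome biogenesis genes had less, and each of these lists had adjusted p = 0.924 with an estimated correlation. By label, the Hox, granulocyte and stem cell lists therefore went the opposite way to H3K27ac, and by the genotype in the peak names they went the same way. In limma 0 of 15796 genes passed, with 760 at an unadjusted p under 0.05. The split by replicate number called 3 genes, the Y-linked Ddx3y, Eif2s3y and Kdm5d, and the crossed split 0 (567 and 762 unadjusted). Camera called 6 lists by label, but 8 in the crossed split and 4 by replicate number, so the list calls below do not exceed those of a split without genotype.

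B-lymphoid genes shifted up in the libraries labelled Tg (median 0.27, camera adjusted p = 8.91e-06), higher for 18 of 18 genes. Mature granulocyte genes (0.36, 8.91e-06) were higher for 15 of 15, and erythroid genes (0.14, adjusted p = 0.00130) for 18 of 22. Ribosome biogenesis (-0.10, adjusted p = 0.000196), Hox (-0.28, 0.00255) and stem cell genes (-0.14, 0.0400) shifted down. All 6 had an adjusted p = 0.924 with an estimated correlation. Only the ribosome biogenesis call held without any single library (0.000834 to 0.0149). Without the library labelled Tg replicate 1 the B-lymphoid and granulocyte lists had an adjusted p of 0.0929, and the Hox (median 0.03, 0.608) and stem cell (median 0.00, 0.839) lists turned up. Without the one labelled WT replicate 1 the erythroid and stem cell lists had an adjusted p of 0.308 and the Hox list 0.0631. Adjusted over the list alone, Cd74 (B-lymphoid) and Retnlg (granulocyte) rose by label, and 0 members of the other 4 lists passed. Over all genes 0 did, with Cd74 at 1.40 (limma adjusted p = 0.692), Il7r at 1.23 (0.917), Pax5 at 0.77 (0.917), the erythroid gene Alas2 at 1.38 (0.917), Hoxb6 at -0.80 (0.917) and Wdr12 at -0.19 (0.917).

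The other 14 lists did not pass in H3K4me3. Medians were -0.03 for myeloid progenitor, -0.05 for leukaemia, -0.02 for JAK-STAT, 0.04 for cell cycle, 0.02 for p53, 0.01 for interferon, 0.07 for NK cell, 0.02 for mast cell and -0.22 for stroma genes. Median and mean differed in sign for the NuRD (-0.02 and 0.02, test up), megakaryocyte (0.05 and -0.00, up), monocyte (-0.06 and 0.00, down), T-lymphoid (0.00 and -0.01, down) and NF-kB lists (0.00 and -0.01, up). Adjusted over the list alone Col1a1 of the stroma list rose and Cxcl12 fell, by label, and over all genes 0 of these lists' members did.

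Of 44957 H3K4me3 regions 24578 (54.7%) were in all 4 libraries. Those only in the libraries labelled WT numbered 1008, with Cfap300 (chromosome 9, 8017566 to 8017858), Phf6 (chromosome X, 52916516 to 52916798 and 52931498 to 52931783), Noc4l, Otud7a and Noxa1 among the nearest genes to the strongest. Those only in the libraries labelled Tg numbered 661, with Tomm7 (chromosome 5, 23831407 to 23831714), Sec24b and Rhou among the nearest, and regions in Nos1ap (chromosome 1, 170545557 to 170545985) and Ptprm (chromosome 17, 67193913 to 67194709) the strongest away from gene ends. The peaks in the named Phf6 regions stood on a local background of 9.61 to 10.1 times the list median. They are therefore not read here as a gain of H3K4me3 alone. The other splits gave 392 and 975 regions by replicate number and 1210 and 505 when crossed. With lists of equal length the order turned, to 702 for labelled WT and 819 for labelled Tg. Leaving out a library changes both rules unequally, and gave 1861 for labelled WT and 2837 for labelled Tg without Tg replicate 1, 2793 and 3828 without Tg replicate 2, 3147 and 1955 without WT replicate 1, and 6114 and 1234 without WT replicate 2. Peak number was 38366 ± 1723 in libraries labelled WT and 35798 ± 1242 in those labelled Tg (log2 -0.10, exact permutation p = 0.333, the smallest possible). Near gene ends lay 35.9% ± 1.88 and 36.8% ± 0.0960 of peaks (exact permutation p = 1). The Jaccard index was 0.771 within and 0.769 between genotypes.

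Combining the marks asks whether enhancers changed together with promoters. Most H3K27ac regions of a single genotype over 1 kb from every gene end lay where H3K4me1 was present in every library. Of 834 such Tg-only regions, 64.1% had H3K4me1 in all 4 libraries, 0.480% only in Tg, 0.360% only in WT and 13.1% in none. Of 2173 such WT-only regions, 59.4% had it in all 4, 0.414% only in WT, 0.368% only in Tg and 12.3% in none. H3K4me3 was present in all 4 libraries at 20.7% of the 834 Tg-only and 12.3% of the 2173 WT-only H3K27ac regions, so some may be promoters, which was not tested. Distal active regions numbered 4504 in WT and 3306 in Tg, with 1613 shared (log2 -0.45), where H3K4me3 was taken by label. With the H3K4me3 genotypes exchanged there were 4289 and 3227 (log2 -0.41), and regions without H3K4me3 in any of the 4 libraries, which need no label, numbered 3585 and 2602. The order of WT and Tg turned without replicate 1 of every mark (7650 in WT, 9615 in Tg, log2 0.33) and was 11072 and 5552 without replicate 2.

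Genes near WT-only H3K27ac regions were more often than by chance near H3K4me3 regions present only in the libraries labelled Tg (68 of 994 genes against 30.2 by chance, odds ratio 2.63, Fisher's exact adjusted p = 1.65e-09). Genes near Tg-only H3K27ac regions overlapped likewise with H3K4me3 regions only in the libraries labelled WT (40 of 500 genes against 20.4, odds ratio 2.14, adjusted p = 0.000249), which was lost at the stricter peak threshold (odds ratio 1.42, adjusted p = 0.405). The pairings by the same label did not pass, with 19 genes against 15.2 for Tg (1.28, adjusted p = 0.383) and 54 against 40.5 for WT (1.39, 0.0705). H3K27ac and H3K4me1 Tg-only regions shared 57 genes against 41.2 (1.46, adjusted p = 0.0501) and WT-only ones 156 against 163 (0.943, 0.640). H3K4me1 and H3K4me3 regions of the same label shared 40 genes against 33.7 for Tg (1.22, 0.355) and 82 against 97.5 for WT (0.811, 0.183). The remaining 4 pairings, of opposite labels with H3K4me1, had odds ratios from 1.01 to 1.34 and adjusted p of at least 0.0705. Across 12823 genes the changes of H3K27ac and H3K4me3 had a Spearman correlation of -0.215. For H3K27ac and H3K4me1 it was -0.0491 over 12892 genes, and for H3K4me1 and H3K4me3 it was -0.0115 over 14927.

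**Figure D5:**
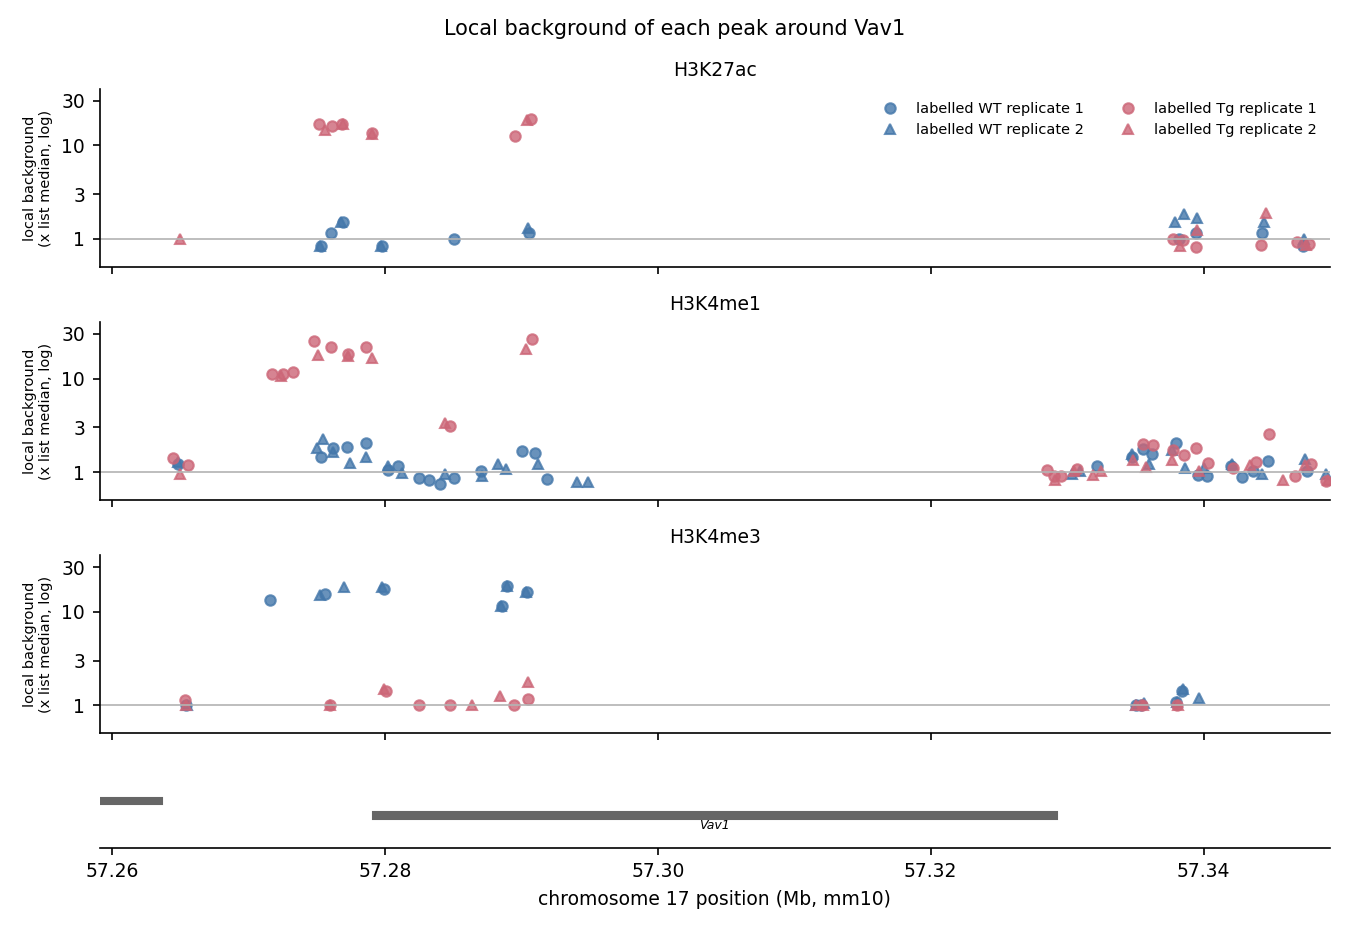
Local background of each peak relative to its own list's median (vertical log axis) along chromosome 17 (Mb, mm10) around Vav1, for the 3 marks; points are peaks of the 4 libraries of a mark. Within 10 kb of the Vav1 start the background averages 15.4 in H3K27ac Tg, 16.0 in H3K4me1 Tg and 16.8 in H3K4me3 libraries labelled WT, and it stays near 1 in the others.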

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

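All tests in this part were chosen only after the result was seen, except the correlation between H3K4me3 and H3K27ac changes, whose prediction was written before.

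The 4 H3K4me3 lists draw attention because their peak names, which set the groups of no main comparison, carry the other genotype than their labels. The local background, also outside the main comparison, differs in the same manner around the Vav1 start (chromosome 17, gene 57279100 to 57329236). It was 15.4 ± 1.37 in the Tg libraries of H3K27ac against 0.917 ± 0.118 in WT, and 16.0 ± 1.37 against 1.13 ± 0.113 in H3K4me1 (SD, n = 2 each). In H3K4me3 it was 16.8 ± 1.84 in the libraries labelled WT against 1.06 ± 0.0890 in those labelled Tg. Inside Phf6 the H3K4me3 peaks of the libraries labelled WT stood on a background of 9.86 ± 0.150, and those labelled Tg had 0 peaks there. At the far end of Vav1 the background was near 1 in every group, from 0.909 to 1.33.

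A candidate explanation is that the genotype labels of the 4 H3K4me3 libraries are exchanged. The H3K4me3 change correlated with the H3K27ac change at -0.215 across genes, the sign such an exchange predicts, but the crossed split of the H3K4me3 libraries correlated as strongly (0.220), so that test alone leaves the question open. If the transgene carries extra copies of Vav1 and Phf6 sequence, the libraries that hold it should stand out in background at Vav1. The lower of the libraries labelled WT stood 13.8 times above the higher of those labelled Tg in H3K4me3, and the other marks gave at least 12.5 times the opposite way. That the peak names alone are wrong is argued against by this ratio, and a gain of signal confined to Vav1 would not account for the background inside Phf6, which in H3K4me1 was also raised in Tg (6.02 ± 1.48, against 0.787 in the single WT library with a peak there). Whether extra copies or another cause raise the background at both loci stays open, since the control library is not stated and the labels do not describe the transgene's sequence.

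WT-only H3K27ac regions outnumbered Tg-only ones 2.53 to 1. A longer list in WT replicate 1 could produce this. With all lists at 31257 peaks the ratio was 2.63, which argues against list length as the whole cause. The wider peaks in WT, a difference in enrichment between libraries and the genotype itself stay open, and no biological explanation was tested.

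The replicate 2 lists of H3K4me1 resembled each other (Jaccard index 0.631) more than any other pair, which the replicate 1 lists did not (0.445), and the replicate 2 pair alone had 42.7 times as many regions as the replicate 1 pair alone. Longer peak lists among replicate 2 could produce this. At equal list length the ratio fell to 9.86, still far from even, so length may account for part of it and not all. Differences in depth, enrichment or handling between replicate 1 and replicate 2 stay open. The labels do not give the sex of the mice. Every H3K4me1 library had 0 peaks at Kdm5d, Eif2s3y, Uty and Ddx3y. At Xist the replicate 1 libraries had 1 peak each and the replicate 2 libraries 3 in WT and 6 in Tg. Whether this mark would be called at those Y-linked genes in a male is unknown here. A difference in sex between replicate 1 and replicate 2 of this mark therefore stays open.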

How the results depend on the processing

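Tests chosen only after the result was seen were the whole-gene window, the end with H3K4me3, crossed numbers and the Vav1 and Phf6 exclusion. Also chosen then were lists without normalization, H3K4me3 absent from all libraries or with genotypes exchanged, and overlap tests at other list lengths and thresholds. So was leaving libraries out for the share near gene ends, similarity and distal regions. Of 216 alternatives for the main results, 149 stayed close, 65 moved and 2 became stronger.

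For H3K27ac genes (36), limma called 0 with a 100 bp pseudocount (1417 unadjusted) and 111 with 2000 bp, 3 after scaling, 1 (Tmem45a2) without normalization, 9 without a filter, 8 and 14 with windows of 2 and 50 kb, 0 at the stricter threshold (1583 unadjusted), 8 at equal list length, 5 at the end with H3K4me3 (Abhd6, Lypd10, Lypd11, Olfm4 and Slc46a1), and 0 to 114 with a library left out. Of these, 35 of the 111, 7 each of the 2 kb, 50 kb and equal-length calls, and 1 of the 9 were among the 36. The whole gene gave 51, 33 shared. Without a filter H3K4me1 gave 1 (Myrfl) and H3K4me3 gave 4 (Bglap3, Gdap1, Mal2 and Paqr6). Dnase1l3 turned to 0.31 at 50 kb. Tmem45a2 stayed called in 11 of 14 alternatives, Olfm4 in 10 of 15, Mpo in 4 of 16 and Mmp8 in 5 of 17. The cause was not tested.

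The replicate number as a block gave 6 H3K27ac genes, all falls and all among the 36, and 0 in the other marks. Same-numbered libraries deviated with a correlation of -0.199 in H3K27ac, 0.209 in H3K4me1 and -0.0832 in H3K4me3. Libraries were not treated as pairs because the labels do not say that the numbers pair them, and in H3K4me1 the positive value leaves this open. In H3K4me3 both replicate 1 libraries had Y-linked peaks and 0 at Xist, and both replicate 2 libraries had the reverse. The number there goes with a difference in sex, which the main fit leaves in the spread. The block ended the H3K4me1 NK cell call (adjusted p = 0.0637) and no other list call. Crossed numbers gave 10 H3K27ac genes, 2 up and 8 down, and 0 in the other marks.

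Called lists fell to 0 in each mark with an estimated correlation, a test with few residual degrees of freedom that cannot decide these calls. H3K27ac gave 3 at equal length, H3K4me1 gave 3 without normalization. With a library left out there were 3 to 4 in H3K27ac, 1 to 7 in H3K4me1 and 3 to 8 in H3K4me3. Without the H3K4me3 library labelled Tg replicate 1 list stem cell and self-renewal, H3K4me3, (0.00120) and list Hoxa and Hoxb clusters, H3K4me3, (0.0298) reversed; over all libraries left out they ranged from -0.228 to 0.00120 and from -0.615 to 0.0298. Of 153 alternatives for called lists, 98 kept the call and 53 lost it in the same direction. The cause was not tested.

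Tg-only and WT-only counts moved with presence rules. In H3K27ac, 50% cover gave 4209 WT-only, and the stronger 50% of lists gave 34 and 83. In H3K4me1 the stricter threshold gave 1771 and 2030, the stronger 50% gave 134 and 409, and merging within 500 bp gave 1828 and 2975. In H3K4me3 the stricter threshold gave 370 for labelled Tg and the stronger 50% gave 0 and 5. Fewer peaks entered by construction with the stricter threshold and the stronger 50%, and for the others the cause was not tested. With a library left out, its genotype needs a peak in only 1 library and the other needs absence from only 1, so both counts rise by construction. The ranges were then 1302 to 5179 and 3160 to 12191 in H3K27ac, 3440 to 20415 and 5589 to 26075 in H3K4me1, and 1234 to 3828 and 1861 to 6114 in H3K4me3.

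With a library left out, the difference for similarity of peak sets within against between genotypes, H3K27ac, ranged from 0.00111 to 0.125. The distal log2 ratio then ranged from -0.996 to 0.33. The difference, by label, in the share of peaks at promoters, H3K4me3, became -1.03 points at equal list length. Promoters stand here for 1 kb around either gene end, because start sites were unknown. H3K27ac and H3K4me1 Tg-only regions shared genes past the threshold at equal length (odds ratio 1.74, adjusted p = 0.000180) and the stricter threshold (1.64, 0.0291). Opposite pairings passed too: WT-only H3K27ac with Tg-only H3K4me1 (1.45, adjusted p = 0.0211, stricter), WT-only H3K4me1 with labelled Tg-only H3K4me3 (1.42, 0.0124 at equal length; 1.70, 0.0309 stricter) and Tg-only H3K4me1 with labelled WT-only H3K4me3 (1.57, 0.0287, stricter). Tg-only H3K27ac with labelled WT-only H3K4me3 did not pass at the stricter threshold (1.42, adjusted p = 0.405). The cause was not tested. Depth is unknown, so its limits could not be given.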

Other observations

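Every value in this part was looked up only after other results had been seen.

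Among 10280 tiles of 100 kb with H3K4me3 peaks in all 4 libraries, those with the highest background in both libraries labelled WT over both labelled Tg held Phf6 (chromosome X, 52900001 to 53000000, ratio 7.63) and the start of Vav1 (chromosome 17, 57200001 to 57300000, ratio 6.36). The third stood at 2.13. In the opposite direction the highest ratio was 2.59. In H3K27ac the highest tile in WT over Tg lay at the end of chromosome 19 (61100001 to 61200000, ratio 6.76). In Tg over WT the highest ratios were 1.86 in H3K27ac (chromosome 4, 137500001 to 137600000) and 1.54 in H3K4me1 (chromosome 14, 70400001 to 70500000). Neither the Vav1 nor the Phf6 tile was among the 3 highest there. A tile's value is the median over all its peaks, which can dilute a raised stretch. Within 10 kb of the Vav1 start the background in Tg was 16.8 times that in WT in H3K27ac and 14.2 times in H3K4me1.

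Peaks at the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y occurred in the H3K4me3 replicate 1 libraries of both labels, with 1 peak each except 2 at Uty in the one labelled WT. All other 10 libraries had 0 there. The H3K4me3 replicate 1 libraries had 0 peaks at Xist. In H3K27ac and H3K4me1 all 8 libraries had 1 to 6 peaks at Xist.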
